A study of Mus musculus with 2 samples.

How the data were processed

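MicroRNA sequencing of mouse forebrain at embryonic day 16.5 was represented by 2 libraries, labelled biological replicates 1 and 2, each made from total RNA of forebrain pooled from embryos of both sexes of the B6NCrl strain. The labels give 41 embryos for the pool of replicate 2 and separate biosample records for the 2 pools, and name small RNA below 30 as the size range. Both libraries belong to one group, so the design holds no comparison between groups and no test between conditions was made.

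Each deposited table holds raw read counts per gene in 3 columns, one without regard to strand and one for each strand, and 4 further rows that total unassigned reads. Per the deposited file descriptions, reads were placed on the mm10 assembly with the GENCODE M4 annotation. The aligner, the counting tool, their versions and the adapter trimming are not given in the sources used here. The column without strand equals the sum of the other columns in both tables. The column with the larger total was taken as the gene strand and used as the count of a gene. This choice, the exact binomial test, the measures of spread and agreement, the test of genomic clusters, the gene lists and the rule for naming genes were fixed before the data were examined, with their alternatives. Tests of technical explanations were chosen later. The tables total reads that map to several loci apart from the genes, and for that reason a gene's count is read here as a count of uniquely placed reads. Genes that share a stretch of 22 bases with another miRNA gene on either strand are uncertain, and 880 genes did so.

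The rows of unassigned reads were kept out of library totals and tests. They held 40.5% of all reads as mapping to several loci, 19.1% as unmapped and 2.50% as uniquely mapped outside the listed genes in replicate 1, and 43.3%, 15.2% and 2.82% in replicate 2. The gene-strand totals were 5060112 counts in replicate 1 and 4158686 in replicate 2, a ratio of 1.22. A count of 0 therefore allows up to 0.593 CPM (counts per 1000000 gene-strand counts) of uniquely placed reads in replicate 1 and 0.721 CPM in replicate 2, taking a limit of 3 counts. It sets no limit on the level of a gene whose reads map to several loci. Intervals and limits cover counting error only, since no molecular identifiers are described for these reads.

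Gene symbols, positions, host genes and precursor sequences were taken from GENCODE M21 (GRCm38, the assembly that mm10 names) by gene identifier. A symbol was found there for 1894 genes. The 79 others reached at most 7 counts and are referred to by no name. CPM and shares are relative to the gene-strand total of a library. Values are the mean ± SD of the 2 replicates. Exact Clopper-Pearson intervals at 95% were computed for the share of the most abundant genes.

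The 16 fixed lists of miRNA families cover neural families, 11 other tissues or cell types, and genomic or sequence families. A family was matched by its symbol or an older symbol in the RefSeq table of GRCm38.p6. Mir7j and Mir7k, which that table names as members of the let-7 family, were counted there, and the imprinted list was limited to chromosome 12. A list's median log2(CPM + 1) was set beside that of 10000 random lists of the same size drawn from all genes, most of which had no count, as a description of these libraries. This comparison ranks lists of expressed genes of any kind highly. The rule for naming genes takes the 20 genes with the highest mean share, up to 4 genes of each list with the highest mean share, the 5 highest and 5 lowest ratios between replicates among genes with at least 100 counts in both libraries, and the 3 genes with the highest opposite-strand share, with ties broken by the number of reads. Genes named outside the rule are stated as chosen after their values were seen.

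Genes with a summed count of at least 10 were tested for a difference between the 2 libraries beyond counting noise. The test was a two-sided exact binomial test of the 2 counts given their sum. The expected share came from library totals scaled by the trimmed mean of M values (TMM) in edgeR 4.0.16 under R 4.3.3, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Adjusted p-values below 1e-300 were written as 1e-300. This test compares 2 libraries, not conditions, and treats reads as independent. Log2 ratios were computed after adding 0.5 to each count. The biological coefficient of variation is the square root of the common dispersion that edgeR estimated with both libraries as a single group. It covers genes with at least 5 counts in both libraries, with an interval from 100 bootstrap draws of genes. The quasi-likelihood test of edgeR needs a second group and was not used. Agreement between replicates is given as Pearson's r and Spearman's rho of log2(CPM + 1), without a p-value, because genes are not independent replicates. Genomic clusters join neighbours on one strand whose starts lie within 10 kb.

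The tests were tried on simulated data before use. For the difference between the 2 libraries, 466 genes were drawn without replicate spread. Of the genes changed 2-fold, 77.6% were called, of those changed 4-fold 89.1%, and of unchanged genes 0.72%. A coefficient of variation simulated at 0.3 over 426 genes was recovered as 0.334. Over 139 clustered genes, an intraclass correlation simulated at 0.5 was recovered as 0.623 with a permutation p of 0.001, and one of 0 as 0.121 with a permutation p of 0.061. The alternatives tried were DESeq2 1.42.0 size factors, unscaled library totals, other count minimums and pseudocounts, thinning to the smaller total, unstranded counts, totals with and without particular reads, other cluster distances, and each replicate alone.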

Results

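The data describe the microRNA (miRNA) profile of the mouse forebrain at embryonic day 16.5, a stage at which neurons of the cerebral cortex are being born, in 2 libraries from separate pools of embryos. Replicate 1 held 5060112 and replicate 2 held 4158686 counts on the strand of the annotated miRNA genes. At least 1 gene-strand count in either library was present for 703 genes, and 438 genes had at least 5 counts in both libraries. The remaining 1270 genes had no gene-strand count in either library, which allows up to 0.593 CPM of uniquely placed reads in replicate 1 and 0.721 CPM in replicate 2. Of these genes, 767 share a stretch of 22 bases with another miRNA gene, and a count of 0 sets no upper limit on their level. The labels name no second tissue, stage or treatment, so the questions addressed here are which miRNA genes the forebrain libraries held and how closely the pools agreed.

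By uniquely placed reads, the profile was dominated by few genes, and Mir99a was the most abundant. Reads that map to several loci, 41.9% of all reads on average, are not in this ranking and could change it. Mir99a (ENSMUSG00000065530.1) took 24.96% ± 2.57 of all counts (SD, n = 2). It lies at chromosome 16, 77598936 to 77599000, in an intron of its non-coding host gene Mir99ahg. Genes of the let-7 family followed, a family whose mature forms rise as animal tissues differentiate. Mirlet7g (ENSMUSG00000065440.1), in an intron of Wdr82 at chromosome 9, 106178840 to 106178927, took 7.82% ± 0.0149. Mirlet7i (ENSMUSG00000065406.2), at chromosome 10, 122985640 to 122985724, took 4.52% ± 0.000869. Mir335, in an intron of the imprinted gene Mest, took 3.34% ± 0.583, and Mir100, a close relative of Mir99a, took 2.98% ± 0.237. The 10 most abundant genes together held 55.6% ± 1.54 of the counts, with exact Clopper-Pearson 95% intervals of 54.5% to 54.6% in replicate 1 and 56.7% to 56.8% in replicate 2. The 8 most abundant genes were enough to reach 50% of the counts and the 58 most abundant to reach 90%.

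**Figure D1:**
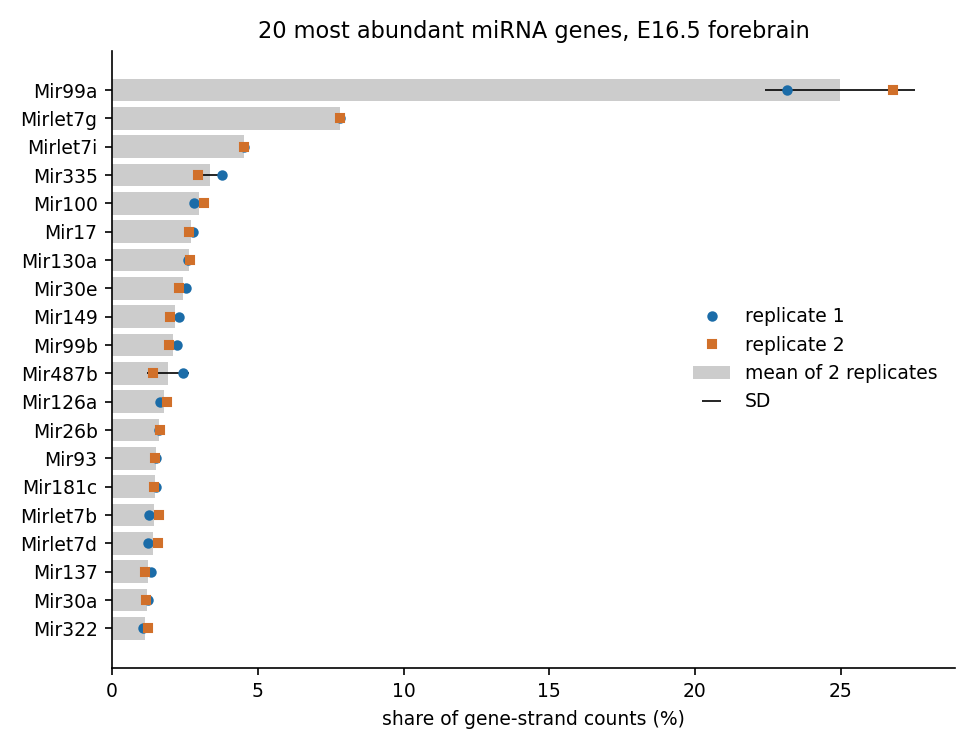
Share of gene-strand counts (percent, x axis) of the 20 most abundant miRNA genes (y axis); bars are means of 2 replicates, points are the replicates and lines the SD. Mir99a stands apart at 24.96%, and the next gene, Mirlet7g, is at 7.82%.

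The other genes among the 20 most abundant each took between 1.14% and 2.70%. Mir17, the first member of a cluster that promotes proliferation of progenitor cells, took 2.70% ± 0.105, and Mir130a took 2.64% ± 0.0410. Mir30e took 2.42% ± 0.184, Mir149 2.14% ± 0.217 and Mir99b 2.09% ± 0.201. Mir487b of the imprinted Dlk1-Dio3 region took 1.93% ± 0.721, and Mir126a, which endothelial cells express and which lies within Egfl7, took 1.78% ± 0.169. Mir26b was at 1.62% ± 0.0398, Mir93 at 1.504% ± 0.0272, Mir181c at 1.46% ± 0.0531, Mirlet7b at 1.43% ± 0.252 and Mirlet7d at 1.41% ± 0.230. Mir137, a regulator of neuronal maturation, was at 1.23% ± 0.126, Mir30a at 1.20% ± 0.0559 and Mir322 at 1.14% ± 0.105. By the GENCODE M21 annotation, 16 of the 20 genes lay within a host gene on the same strand. Of these, 7 overlapped an exon of any annotated host transcript and 9 lay in introns only. Such an overlap does not show that a miRNA is processed from an exon.

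Of the 29 measured genes of the neural list, 28 had at least 5 counts in both libraries and none was at 0 in both. Together they held 4.78% ± 0.463 of the counts (SD, n = 2), and their median level lay at the 100th percentile of random lists drawn from all genes. That percentile does not set the neural list apart, since the lists of other tissues lay between 96.1 and 99.98 on the same measure. Mir137 was the most abundant at 12348 ± 1260 CPM, followed by Mir135b at 6708 ± 938 CPM. Mir125a stood at 5104 ± 737 CPM and Mir92b, abundant in neural progenitors, at 4025 ± 162 CPM. The genes of the neuronal Mir124a family had far lower counts. Mir124a-1 was at 4.27 ± 0.943 CPM, Mir124a-2 at 1.77 ± 0.552 CPM and Mir124a-3 at 1.07 ± 0.158 CPM. Mir9-2 was at 3.62 ± 1.03 CPM and Mir9-3 at 717 ± 27.6 CPM. These 5 genes were named after their values were seen. All 5 share a stretch of at least 22 bases with another miRNA gene, as do 19 of the 29 genes of the list. Reads that map to several loci were totalled apart from the genes, so the levels of such genes are uncertain.

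By uniquely placed reads, the let-7 and miR-98 list held the largest share of the lists, 16.8% ± 0.658 of the counts over 12 genes, 11 of them with at least 5 counts in both libraries. Mirlet7e and Mirlet7f-1, named here after the counts were seen, have no row and are not in the list. Mirlet7g at 78156 ± 149 CPM and Mirlet7i at 45210 ± 8.69 CPM led it, with Mirlet7b at 14314 ± 2521 CPM and Mirlet7d at 14123 ± 2304 CPM behind them. Of this list, 5 genes share 22 bases with another gene, and their levels are uncertain for that reason. The list of the Mir17 to Mir92 cluster and its paralogous clusters, which act in proliferating progenitors, held 6.95% ± 0.114, with all 15 genes detected. Mir17 reached 27023 ± 1052 CPM, Mir93 15041 ± 272 CPM, Mir106b 10093 ± 615 CPM and Mir20a 10089 ± 407 CPM.

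The miRNA genes of the imprinted Dlk1-Dio3 region on chromosome 12, which are expressed from the maternal allele, held 5.56% ± 1.60 of the counts. Of 51 genes, 46 had at least 5 counts in both libraries and 2 had none in either. Genes of the region without a row, such as Mir409 and Mir376a, named here after the counts were seen, are not among them. Mir487b reached 19263 ± 7210 CPM, Mir127 5101 ± 869 CPM, Mir369 4284 ± 1416 CPM and Mir382 3947 ± 1038 CPM. The 69 genes of families that fill an intron of Sfmbt2 held 0.249% ± 0.0177, and 49 of them had no count in either library. Mir467e at 790 ± 37.6 CPM, Mir467d at 705 ± 34.7 CPM, Mir467c at 524 ± 103 CPM and Mir669o at 195 ± 1.18 CPM were the most abundant of them. Of these 69 genes, 67 share 22 bases with another miRNA gene.

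The 11 lists of other tissues and cell types together held 2.94% ± 0.212 of the counts over 62 genes, and the largest single part of that was endothelial Mir126a at 17805 ± 1689 CPM. The list of choroid plexus and ciliated epithelium held 0.501% ± 0.00964, led by Mir449a, a miRNA of multiciliated cells, at 2869 ± 425 CPM and Mir204 at 1453 ± 306 CPM, with Mir34c at 650 ± 20.3 CPM and Mir34b at 26.6 ± 0.148 CPM. The epithelial list held 0.375% ± 0.0458, with Mir429 at 1402 ± 328 CPM, Mir203 at 1338 ± 7.68 CPM, Mir200b at 344 ± 89.9 CPM and Mir200c at 278 ± 59.8 CPM. The sensory organ list of Mir182, Mir183 and Mir96 held 0.0690% ± 0.0203, at 326 ± 67.5, 268 ± 93.9 and 96.4 ± 41.2 CPM. The Hox cluster list, whose genes lie in the Hox clusters that pattern the hindbrain and posterior body, held 0.0630% ± 0.0195, with Mir10a at 356 ± 120 CPM, Mir10b at 228 ± 60.9 CPM, Mir196b at 33.3 ± 11.4 CPM and Mir615 at 9.62 ± 2.04 CPM.

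The oligodendrocyte list held 0.0484% ± 6.96e-05, from Mir338 at 289 ± 2.37 CPM, Mir219a-1 at 166 ± 4.99 CPM and Mir219a-2 at 29.4 ± 8.06 CPM. The erythroid list held 0.0273% ± 0.00463, with Mir451a at 195 ± 60.9 CPM, Mir144 at 56.3 ± 19.3 CPM and Mir486 at 21.4 ± 4.72 CPM. The microglial and myeloid list held 0.0243% ± 0.00510, with Mir223 at 123.9 ± 38.6 CPM, Mir155 at 70.3 ± 0.521 CPM, Mir146 at 47.8 ± 11.4 CPM and Mir146b at 1.34 ± 0.492 CPM. Its member Mir142b had no gene-strand count, and had 926 opposite-strand reads in replicate 1 and 941 in replicate 2. With unstranded counts, which include those reads, the list held 0.0440%. The pluripotency list held 0.0231% ± 0.00992, with Mir302a at 84.3 ± 33.9 CPM, Mir302d at 79.5 ± 36.3 CPM, Mir302b at 53.7 ± 25.6 CPM and Mir302c at 7.35 ± 3.59 CPM, and 3 of its 12 genes at 0. The liver list held 0.0221% ± 0.00339, with hepatocyte Mir122 at 81.4 ± 23.3 CPM, Mir192 at 77.9 ± 0.278 CPM, Mir194-2 at 59.2 ± 9.61 CPM and Mir194-1 at 2.22 ± 0.766 CPM. The muscle list had the lowest share by uniquely placed reads at 0.00443% ± 0.000584, with Mir206 at 22.01 ± 4.58 CPM, Mir208b at 16.4 ± 8.62 CPM, Mir208a at 2.01 ± 0.796 CPM and Mir499 at 1.79 ± 0.827 CPM, and 4 of its 10 genes at 0. Of these 10 genes, 4 share 22 bases with another gene, among them Mir133a-1, Mir133a-2 and Mir1a-1 at 0, so the low share of this list and the zeros of these genes are uncertain. These 3 genes were named after their values were seen. Among the lists of other tissues, such sharing also holds for 2 genes each of the oligodendrocyte, liver and Hox cluster lists.

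**Figure D2:**
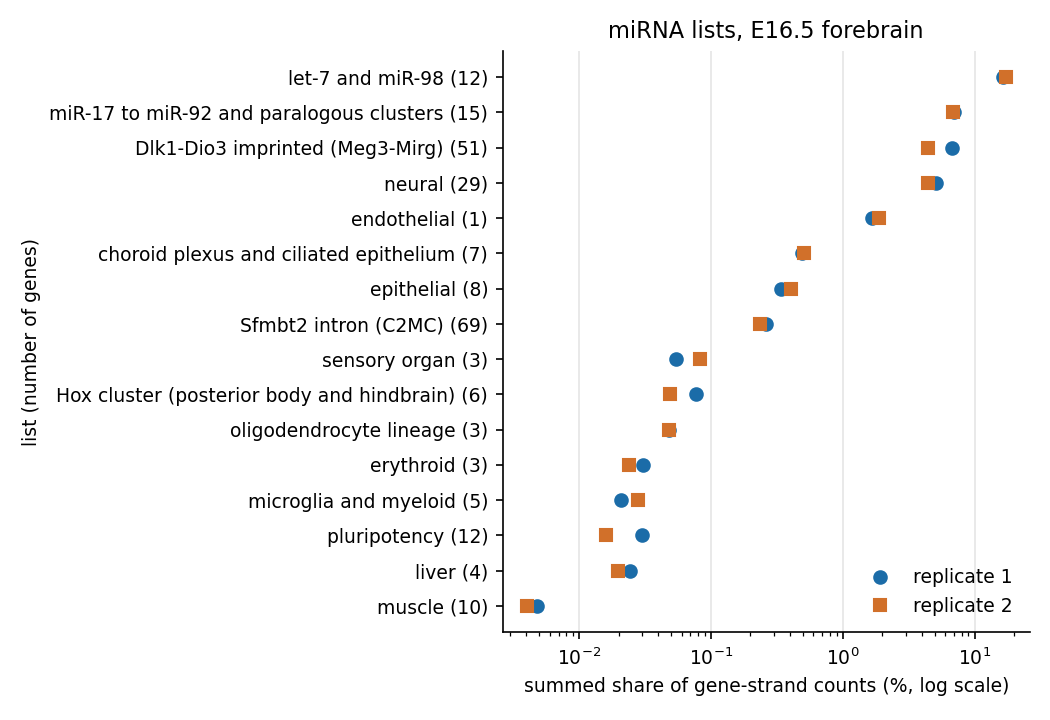
Summed share of gene-strand counts (percent, log scale, x axis) of each miRNA list (y axis, with its number of genes) in replicate 1 (circles) and replicate 2 (squares). Shares run from 0.00443% for the muscle list to 16.8% for the let-7 and miR-98 list, as means of the 2 replicates.

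Levels of the miRNA genes with at least 5 counts in both libraries were close in the replicates. Across these 438 genes, Pearson's r of log2(CPM + 1) was 0.994 and Spearman's rho 0.988, where genes are not independent replicates. Across all 703 genes with a count in either library, r was 0.994 and rho 0.9501. The biological coefficient of variation was 18.1%, with a bootstrap interval over genes of 17.0% to 19.3%. This interval takes genes as independent and rests on 2 pools, so it does not measure uncertainty about the spread between pools. On simulated data, a coefficient of 0.3 was recovered too high, as 0.334. Of 273 genes with at least 100 counts in both libraries, 217 lay within 0.5 of each other on the log2 scale and 272 within 1. The exact binomial test called 211 of 466 genes at an adjusted p under 0.05, 109 of them higher in replicate 2 and 102 lower. This test takes reads as independent and allows for no spread between pools, so its calls describe these 2 libraries only. With unscaled library totals in place of TMM, every log2 ratio shifted by -0.14, and 67 of 222 calls were higher in replicate 2 and 155 lower.

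Within some lists the differences between the libraries went one way. In the Dlk1-Dio3 list, 36 of 47 tested genes were lower in replicate 2 and 0 were higher, or 38 lower and 0 higher when adjusted over the list alone. Mir487b had a log2 ratio of -0.64, Mir369 of -0.54, Mir382 of -0.40 and Mir127 of -0.21, all called by the exact binomial test. The list's median log2 ratio was -0.38 with TMM, and -0.52 with unscaled totals. In the let-7 and miR-98 list, 10 of 11 tested genes were higher in replicate 2 and 1 was lower, the same counts as when adjusted over the list alone, with a median of 0.34. With unscaled totals the median was 0.20 and 8 genes were higher and 1 lower, since the log2 ratios of Mirlet7g and Mirlet7i, both 0.14 with TMM, are no larger than the shift between the scalings. The pluripotency list had 4 of 7 tested genes lower and 0 higher, and the Hox cluster list 3 of 5 lower and 0 higher, with the same counts adjusted over each list alone. The epithelial list had 6 of 8 genes higher and 1 lower, or 4 higher and 2 lower with unscaled totals, and the sensory organ list had all 3 higher under both scalings, with the same TMM counts adjusted over each list alone. The called pluripotency genes all lie in the Mir302 cluster, and the sensory organ genes form a single cluster. With TMM, all epithelial genes called higher except Mir203 lie in clusters with Mir200 genes. Such neighbours are not independent observations. In the neural list, 14 of 29 genes were lower and 5 higher, the same as adjusted over the list alone. The Mir17 to Mir92 list had no direction that held under both scalings: 8 of 15 genes were higher and 1 lower with TMM, also when adjusted over the list alone, and 2 were higher and 7 lower with unscaled totals. Its median was 0.06 with TMM and -0.08 with unscaled totals. The medians also changed sign for the oligodendrocyte list (0.13 and -0.02), the choroid plexus list (0.08 and -0.06) and the Sfmbt2 list (0.10 and -0.04).

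In the remaining lists few genes were called. The oligodendrocyte list had 1 of 3 higher and 0 lower, or 2 higher when adjusted over the list alone. The microglial and myeloid list had 2 of 4 tested genes higher and 0 lower, the erythroid list 1 of 3 higher and 1 lower, and the endothelial gene was higher. The muscle list had 1 of 5 higher and 1 lower, the liver list 0 of 4 higher and 1 lower, the choroid plexus list 1 of 7 higher and 1 lower, and the Sfmbt2 list 0 of 10 higher and 1 lower. With unscaled totals the muscle list had 0 higher, the liver list 2 lower and the Sfmbt2 list 3 lower. Apart from the oligodendrocyte list, the counts of these lists adjusted over the list alone were identical.

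**Figure D3:**
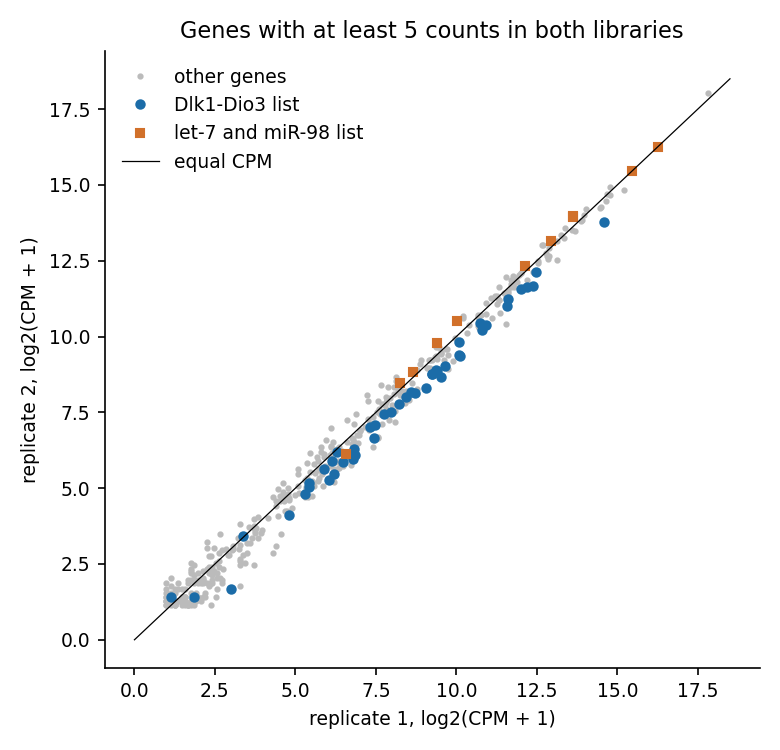
Level of each gene in replicate 1 (x axis) against replicate 2 (y axis), both as log2(CPM + 1), for the 438 genes with at least 5 counts in both libraries; the line marks equal CPM. With these unscaled totals, 39 genes of the Dlk1-Dio3 list (blue circles) were called lower in replicate 2 and 0 higher, and 8 genes of the let-7 and miR-98 list (orange squares) were called higher and 1 lower.

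The genes that differed most between the libraries, among those with at least 100 counts in both, were Mir96 on the higher side and Mir7b on the lower side. Mir96, expressed in sensory hair cells, was higher in replicate 2 by a log2 ratio of 1.04, with an adjusted p of 3.38e-25 by the exact binomial test. Mir214 followed at 0.99, Mir183 at 0.88, Mir144 at 0.86 and Mir223, a miRNA of myeloid cells, at 0.79. Mir7b, enriched in neurons of the hypothalamus, had a log2 ratio of -0.97, with an adjusted p at 1e-300, the lowest written. Mir135a-1, which shares 22 bases with another gene, had a ratio of -0.91, Mir302b of -0.86, Mir302d of -0.82 and Mir383 of -0.79. All of these were called by the exact binomial test, with 1.32e-10 for Mir144 and 9.20e-10 for Mir302b the largest adjusted p-values.

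**Figure D4:**
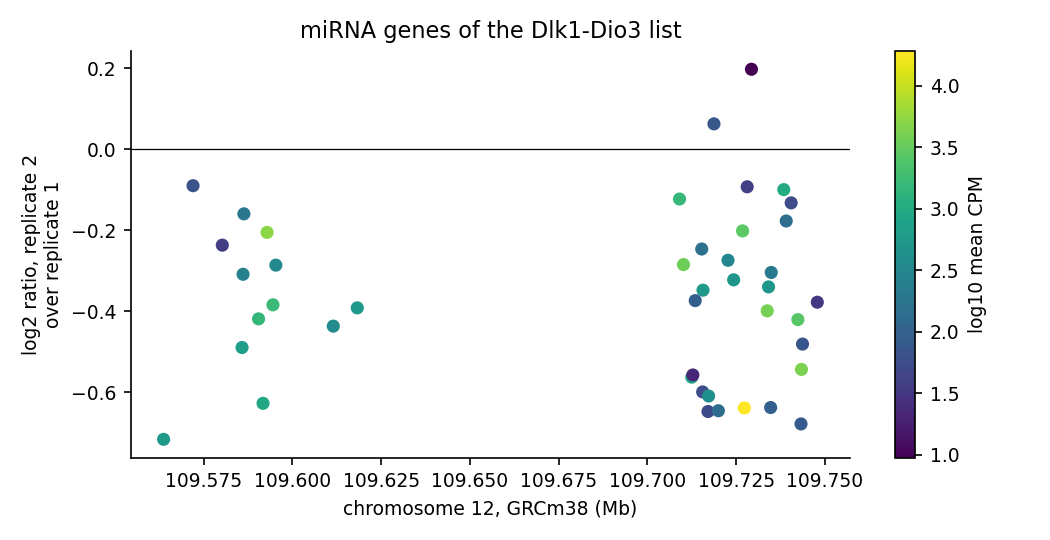
Log2 ratio of replicate 2 over replicate 1 with TMM scaling (y axis) of the 43 genes of the Dlk1-Dio3 list with at least 20 counts in both libraries, by position on chromosome 12 (GRCm38, Mb, x axis); colour gives the log10 mean CPM. Of these genes, 41 lie below 0.

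Reads fell almost entirely on the annotated strand of the miRNA genes. The gene strand held 98.1% of the counts in replicate 1 and 98.3% in replicate 2. Among the 100 most abundant genes the median opposite-strand share was 0% and the highest 1.64%. The opposite-strand counts were concentrated at 11 genes, which held 99.7% ± 0.00310 of them (SD, n = 2). The 3 genes with the highest opposite-strand share were Gm25927, Gm24321 and Gm24083, each with 100% of its reads on the opposite strand. Gm25927 (chromosome 17, 17830343 to 17830459) had 28720 opposite-strand reads in replicate 1 and 24709 in replicate 2. Gm24321 (chromosome 12, 109743158 to 109743237) had 20567 and 9997, and Gm24083 (chromosome 9, 108568295 to 108568414) had 16159 and 12493.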

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

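All tests in this part were chosen after the counts they concern had been seen. The reads described here lie outside the gene-strand counts used in the comparisons, and each kind held a signal above the limit that a count of 0 allows.

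The first is the opposite strand of 11 miRNA genes, given here as mean CPM relative to the gene-strand total and with the miRNA gene that GENCODE M21 places on the other strand. Gm25927 had 5809 opposite to Mirlet7e, Gm24321 had 3234 opposite to Mir409, Gm24083 had 3099 opposite to Mir191, and Gm25252 had 2651 opposite to Mir376a. Gm25301 had 1430.0 opposite to Mir378a, Mir497b had 773 opposite to Mir497, and Gm25750 had 442 opposite to Mir380. Mir299b had 439 opposite to Mir299a, Mir142b had 205 opposite to Mir142, Gm24111 had 174 opposite to Mirlet7f-1, and Gm25641 had 91.5 opposite to Mir9-1. Mir142 is a miRNA of blood and microglial lineages, while the gene-strand count of Mir142b was 0 in both libraries.

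Incomplete strand marking of the libraries is argued against by the 100 most abundant genes, whose median opposite-strand share was 0%. A candidate explanation is that these reads come from miRNA genes on the other strand that had no row among those used here. Such a gene lay opposite 100% of the 11 genes, against 16 of the 299 other genes with at least 100 counts (Fisher's exact test, two-sided, p = 2.45e-13), and 0 of the 11 had a row in the tables used. The position of single reads was not used here, and no biological explanation was tested.

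The second is the reads that map to several loci, 41.9% of all reads on average, against 37.2% and 37.9% of all reads counted on gene strands in replicates 1 and 2. The third is the uniquely mapped reads outside the listed genes, 2.66% of all reads.

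The reads that map to several loci bear on the levels of Mir9 and Mir124a genes: among 703 genes with a count, Mir124a-1, Mir9-2, Mir124a-2 and Mir124a-3 ranked 338, 350, 412 and 464 by mean CPM, and Mir9-3 ranked 99. The loss of such reads is a candidate explanation: all 5 genes share at least 22 bases with another miRNA gene, and within genomic clusters genes that share such a stretch lay below their neighbours by a median of -2.18 on the log2 scale, in 21 of 28 clusters (one-sided permutation p = 0.001, the smallest that 1000 permutations can give). With a stretch of 18 bases the median was -1.40 over 29 clusters (permutation p = 0.003). For example, Mirlet7c-1 had 784 ± 150 CPM beside 249634 CPM for its neighbour Mir99a, and Mirlet7a-1 had 431 ± 37.5 CPM beside 14123 CPM for Mirlet7d. A low level of the miRNAs themselves stays open, and no biological explanation was tested, since the reads that map to several loci are not split by gene in the tables used.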

How the results depend on the processing

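No test in this part was chosen after its result was seen. Shares of counts depend on what they are divided by. With Mir99a left out of the genes and the total, the 10 most abundant remaining genes, Mir487b now among them, held 43.4%. The neural list then held 6.36%, the let-7 list 22.4% and the Mir17 to Mir92 list 9.27%. The Dlk1-Dio3 list held 7.38% and the combined lists of other tissues 3.92%. With unassigned reads and reads that map to several loci in the total, the original 10 genes held 20.9%. The lists, in the same order, held 1.79%, 6.31%, 2.61%, 2.08% and 1.10%. These changes follow from the construction of the total and, for the 43.4%, also from the change of genes. Unstranded counts moved the Mir17 to Mir92 list to 6.83% and no other of these shares by more than the SD. They add no reads of genes outside the lists, such as the opposite-strand reads of Gm25927 (5809 CPM, at Mirlet7e) and Gm24321 (3234 CPM, at Mir409). The check does not cover such reads. Among the 12 single lists of the other kinds, unstranded counts moved 2 (microglia and myeloid to 0.0440%, oligodendrocyte to 0.0476%), the total without Mir99a moved 11 and the total with unassigned reads moved 12. With 2 replicates each one lies within 1 SD of their mean by construction, so leaving one out says nothing about the stability of the shares. A minimum of 50 counts in both libraries left 289 detected genes in place of 438, by its construction. Pearson's r was 0.993 with a pseudocount of 0.1 CPM, 0.996 with 10 CPM and 0.992 with at least 50 counts in both. The coefficient of variation was 0.196 with unscaled library totals, against 0.181, and the cause was not tested. The number of genes called between the libraries ran from 200 to 225 over its alternatives, against 211. Of these calls, 30.2% were higher in replicate 2 with unscaled totals, against 51.7% with TMM and 50.9% with DESeq2 size factors. No paired analysis was possible because the series holds 1 group. Depth limits genes below about 0.721 CPM of uniquely placed reads, and the test on simulated libraries without replicate spread missed some genes changed 2-fold.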

Other observations

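In this part, the test of sequence similarity was chosen after the correlation within clusters was known, and its repeat without the Dlk1-Dio3 genes, the comparisons with genes of like GC content and like expression, the comparison of Mir144 with Mir451a and the opposite-strand ratios were chosen after the data had been seen.

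Some genomic clusters were higher or lower in one library as a whole. The Mir302 cluster on chromosome 3, which marks early embryonic cells, had a mean log2 ratio of replicate 2 over replicate 1 of -0.81 over 4 genes. The Mir182, Mir96 and Mir183 cluster had a mean of 0.83, the Mir429, Mir200a and Mir200b cluster 0.60, and the pair Mirlet7c-2, which shares 22 bases with another gene, and Mirlet7b 0.57. Each gene that enters these means was called by the exact binomial test. The highest mean of all clusters, 0.90, was that of the pair Mir199a-2 and Mir214, which is not among them. Mir199a-2, with 23 and 30 counts, also shares 22 bases with other genes and was not called (adjusted p of 0.104, exact binomial test). Genes here that the rule for naming genes does not take were named after their values were seen.

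A hypothesis of the analysis plan was that miRNA genes of one cluster deviate together between replicates; the intraclass correlation of their log2 ratios was 0.741 over 139 genes in 40 clusters (one-sided permutation p = 0.0001, the smallest that 10000 permutations can give), and 0.679 to 0.771 under its 4 alternatives. The permutation moves genes between clusters within a single pair of pools. Its p therefore does not measure whether clusters deviate together between other pools. The Dlk1-Dio3 genes, whose lower counts in replicate 2 had been noticed before these tests, had a median ratio of -0.37. It lay -0.44 from random lists of genes of like precursor GC content and -0.43 from those of like expression, whose 2.5th percentiles were both -0.04. Those lists draw genes singly, whereas the Dlk1-Dio3 genes lie in few clusters. The percentiles are therefore too narrow for genes that deviate together. The medians of the matched lists, 0.06 and 0.05, argue against precursor GC content and depth, which would move such genes alike. GC content of the reads themselves was not examined. Reads shared between near-identical genes are argued against by a difference of -0.44 from other genes over the 42 members that share no stretch of 22 bases, while removing a linear GC trend (-0.44) and thinning to one total (-0.41) decide nothing, since the first moved hardly any gene and the second scales all genes alike. An intraclass correlation of 0.711 over 77 genes that share no stretch of 10 bases argues against sequence similarity between neighbours as the whole cause. Without the Dlk1-Dio3 genes this correlation was 0.372 over 52 genes (permutation p = 0.015), so much of it rests on that region. With similar neighbours kept, the correlation without that region was 0.679 over 97 genes. The fall from 0.679 to 0.372, over different sets of genes, leaves open a part for sequence similarity outside the region. A difference between the embryo pools in tissue composition or in transcription of the clusters may account for the pattern, as may an unrecorded difference in library preparation, and no biological explanation was tested.

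The pair Mir144 and Mir451a departed from this pattern. Their starts lie within one cluster on chromosome 11, yet Mir144 had a log2 ratio of 0.86 and Mir451a of -0.50, with adjusted p-values of 1.32e-10 and 3.23e-12 by the exact binomial test. Opposite-strand reads at genes in the Dlk1-Dio3 region had log2 ratios of -0.61 (Gm24321), -0.36 (Gm25750), -0.17 (Gm25252) and -0.09 (Mir299b). Among the mostly opposite-strand genes outside the region, Gm25641 was at -0.40 and the rest lay between 0.06 and 0.56.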
